A study of Mus musculus with 8 samples.

How the data were processed

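RNA was sequenced on a DNBseq platform from primary mouse embryonic fibroblasts at passage 2, taken from wild-type and Cbx2 knockout embryos at embryonic day 18, with 200000 cells per library and about 4.62 Gb per library, per the labels' protocols. There were 2 RNA libraries and 2 ATAC-seq libraries per genotype, grouped by the genotype in their labels. Accessibility values are not analysed here. Nothing in the labels says whether the libraries of a genotype came from separate embryos.

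The single table used here was made by the authors. Its 2 expression columns hold a normalised read signal, deposited by the authors as 1 value per genotype. The mean of both columns is the mean of the scaled reads over all 4 libraries, and their ratio is the deposited fold change, so a column is not the mean of the reads of its genotype. Per the submitters' processing notes, HISAT2, Bowtie2, RSEM and DESeq2 were used with the mm10 genome, and their versions, roles and filters are not given in the sources used here. The log2 fold changes are as deposited by the authors and equal the log2 ratio of their columns to within 9.13e-09. They are shrunken toward 0 in genes with few reads. Among genes that differed 2-fold or more by the recovered reads described below, the deposited log2 fold change had a median of 32.5% of that of the reads at a mean up to 5 (305 genes), 66.1% between 10 and 20 (143 genes) and 84.7% between 30 and 50 (58 genes). Above 50 this could not be measured. The p-value column and the adjusted p-values were deposited by the authors from their DESeq2 comparison, and the adjusted values equal the Benjamini-Hochberg adjustment over all 17441 genes to within 1.33e-06. The deposited up and down calls match an adjusted p of 0.05 with an absolute log2 fold change of 1 in all genes. No gene has a value of 0.

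Counts per library were assumed possible before the data were examined, but the table holds values per genotype, so the authors' own test was used as planned for that case. A gene was called where the deposited adjusted p was under 0.05, with the sign of the deposited fold change. A standard error was implied from the fold change and the deposited p, on the same shrunken scale. Its median on the log2 scale was 0.41 for genes with a mean value up to 10, 0.14 between 100 and 1000, and 0.038 above 10000. In 2032 genes with a mean above 2000 the implied coefficient of variation between libraries of a genotype had a median of 3.47%.

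Gene identifiers were matched to a RefSeq table of the GRCm38.p6 assembly, which found 17400 of them, 16683 with the same symbol. Symbols of 26 genes had been turned into dates and were restored by identifier. Gene lists were fixed before the data were examined and tested with limma cameraPR (limma 3.58.1, R 4.3.3) on signed z values from the deposited p, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 38 lists with 3 or more tested members. Correlations within sets could not be estimated, since no values per library were given for all genes. The X inactivation list had 1 tested member and the list of mitochondrial transcripts had 0, so neither was tested. Counts of list members are also given adjusted over the list alone.

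The genes named were set by a rule fixed before the data were examined. It takes Cbx2, the 8 largest rises and 8 largest falls among called genes whose higher group value was at or above the median of that value (247), without predicted-gene names, and up to 3 called members of each list with the smallest adjusted p. It also takes Xist, every Y-linked gene, and every Hox gene and cell cycle inhibitor called, 96 genes besides Cbx2 in all. Some genes that the rule takes are not reported here. Genes named outside the rule were chosen after their values were seen.

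The mean of the 2 columns is a sum of whole reads, each worth a fixed step per library. For all 6126 genes with a mean under 50, 35.1% of genes, exactly 1 set of whole reads in the 4 libraries matched within a tolerance of 6e-09. Shifted decoy values had a match in 0%, 0.667% and 3.67% of cases for means up to 15, 30 and 50. The order of the libraries within a genotype is not known. The recovered size factors were 1.01 and 0.935 in wild type and 1.03 and 1.03 in knockout. The libraries of a genotype differed beyond sampling noise (mean chi-square per gene 1.28 over 2352 wild-type genes, p = 3.68e-19 in a chi-square test, and 1.24 over 2602 knockout genes, p = 3.34e-16 in a chi-square test), so they were not counted as 1 library.

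Each step was tested on simulated data. Recovery of reads was right in 100% of 600 simulated genes for knockout versus wild type. With 17441 genes simulated in 50 rounds, the set test found 199 of 200 lists shifted by a z of 1 and called 7 of 1595 unshifted lists. The simulated z values were normal and independent between genes, so this does not show the error rate where genes are correlated. The limma test on recovered reads, simulated over 3290 genes with 200 changed 4-fold, found 56% of them and called 0 unchanged genes. The test with added spread, simulated over 17441 genes with 200 changed by 2 on the log2 scale, found 95% of them and called 12 others. The spread was simulated as that test assumes it, so this does not show whether it holds for these cultures. Enrichment of annotation terms over 12446 genes found 20 planted terms in 20 rounds and called 0 unrelated terms. Its other called genes were drawn whatever their expression, so this does not show the error rate where calls depend on expression.

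Alternatives were other thresholds, filters and adjustments, recentred fold changes, a pseudocount of 1, and other set tests, all listed before the data were examined. Added later were a spread of 10% or 20% between cultures of a genotype on top of the implied error, limma on recovered reads, and the removal of macrophage lists and copy pairs. Terms of the table's gene ontology column (1885 terms of 10 to 500 genes) were tested with Fisher's exact test against all 12446 annotated genes, with no filter on expression. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.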

Results

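The transcriptome of mouse embryonic fibroblasts lacking Cbx2 was compared with that of wild-type fibroblasts from littermates. Cbx2 is a chromodomain subunit of polycomb repressive complex 1, a chromatin complex that keeps developmental genes silent. Primary fibroblasts were taken at embryonic day 18 and grown for 2 passages. RNA was sequenced from 2 libraries of each genotype, at about 4.62 Gb of sequence per library. Chromatin accessibility (ATAC-seq) was also profiled in 2 libraries of each genotype, and those values are not analysed here. The authors' deposited table lists 17441 genes with 1 normalised expression value per genotype. Its wild-type values sum to 19428299 and its knockout values to 18910077. All group values, log2 fold changes and adjusted p-values of single genes below are those of the authors' deposited table, from the authors' DESeq2 comparison, with no SD because each genotype has a single value. Where reads are few, these fold changes are pulled toward 0 and the values of both genotypes toward each other, so that they understate the difference in reads.

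The targeted transcript was strongly reduced. Cbx2 (gene 12416, chromosome 11 from 119023019 to 119031275 in mm10) had a value of 346.8 in wild type and 29.0 in knockout in the authors' deposited table. Its log2 fold change was -3.58, with a standard error of 0.25 implied by the deposited p, and the authors' DESeq2 adjusted p was 2.55e-44. A value for the whole gene does not show how much or which part of the transcript remained. Whether the knockout value was pulled toward that of wild type could not be measured, as the mean was above 50. Among 35 polycomb complex genes, 2 rose and 1 fell, with 2 and 1 when adjusted over the list alone. Cbx2 itself was the gene that fell. Ring1 (log2 fold change 0.76) and Jarid2 (0.42), subunits of polycomb repressive complexes 1 and 2, rose in the authors' deposited table. The list as a whole did not pass limma cameraPR (adjusted p = 0.351).

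Loss of Cbx2 was accompanied by many modest changes and a few large ones. By the set test, the lists of fibroblast and matrix genes and of glycolysis and hypoxia genes were shifted down, and those of macrophage markers and p53 targets up. In all, 1357 genes (7.78%) passed an adjusted p of 0.05 in the authors' deposited table, with 607 higher and 750 lower in knockout. The median log2 change was 0.63 among genes that rose and -0.39 among genes that fell, and 805 of the calls were under 1.5-fold. A change of 2-fold or more was reached by 175 higher and 119 lower genes, so that 59.5% of the large changes were rises against 44.7% of all calls. With genes limited to those with a mean at or above the median, 457 were higher and 696 lower. Rises were thus relatively more frequent among low genes. There the implied standard error is larger (median 0.39 at means of 10 to 100, 0.069 at 1000 to 10000) and only larger changes pass.

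**Figure D1:**
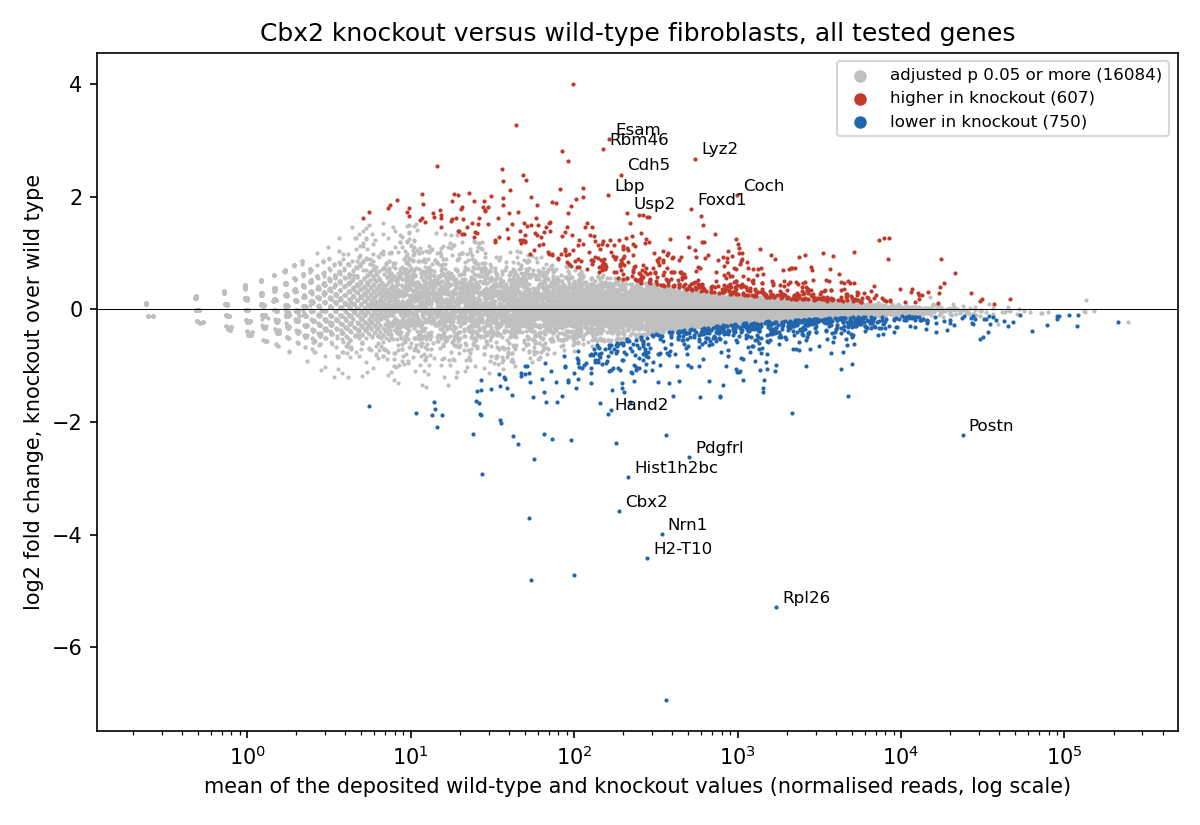
Log2 fold change of knockout over wild type (vertical axis) against the mean of both deposited values on a log scale (horizontal axis), 1 point per gene. Red points are the 607 genes higher and blue points the 750 genes lower in knockout, grey points did not pass, and names mark Cbx2 and the largest changes chosen by a fixed rule.

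Among called genes whose higher value was at or above the median of 247, without predicted genes, the largest rises included genes of blood vessel lining and of innate defence. Esam and Cdh5, adhesion molecules of endothelial cells, had log2 fold changes of 3.03 and 2.40 in the authors' deposited table. Lyz2, the lysozyme of myeloid cells, went from 148 to 947 (log2 fold change 2.68, adjusted p 2.44e-86). Rbm46, an RNA-binding protein, reached 2.85, Coch 2.03, Lbp, which binds bacterial lipopolysaccharide, 2.02, the transcription factor Foxd1 1.78 and the deubiquitinase Usp2 1.72 in the authors' deposited table. Within the same limits the largest falls besides Cbx2 were those of Rpl26 (-5.29), H2-T10 (-4.41), Nrn1 (-3.99), Hist1h2bc (-2.98), Pdgfrl (-2.62), Postn (-2.23) and Hand2 (-1.86) in the authors' deposited table. The values of Rpl26, H2-T10 and Hist1h2bc are uncertain, because these genes have near-identical relatives between which reads could be divided. For Rpl26 the partner Gm15772 moved the other way in the authors' deposited table, from 3438 to 6951, while Rpl26 went from 3376 to 86.1.

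The list of genes that define fibroblasts and build their matrix was shifted down. Of 37 such genes 21 fell and 2 rose, with 23 and 4 when adjusted over the list alone (limma cameraPR adjusted p = 4.09e-35). The median log2 fold change of the list was -0.22, so most falls were small. With the log2 fold change as statistic the cameraPR adjusted p was 7.17e-05. Postn, the matrix protein periostin, dropped from 39240 to 8337, and Dcn, the proteoglycan decorin, from 5774 to 2767 in the authors' deposited table. Thy1, a surface glycoprotein of fibroblasts, went the other way, from 4928 to 11919 (log2 fold change 1.27, adjusted p 2.61e-187). Contractile and smooth muscle genes were divided, with 3 higher and 5 lower of 17, the same counts when adjusted over the list alone (cameraPR adjusted p = 0.0246). There Des, the intermediate filament desmin, fell (log2 fold change -1.05) and so did Myh11 (-0.55), whereas Actg2 rose (0.40) in the authors' deposited table. In cameraPR the contractile call was lost at a correlation of 0.05 (adjusted p = 0.113) and with the log2 fold change as statistic (0.141). It was also lost among genes at or above the median value (0.188) and with 20% added spread (0.0810), and held in the other settings. Macrophage markers moved with these groups in the opposite direction, with a median log2 fold change of 1.63 over 17 genes.

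The list of glycolysis and hypoxia genes was shifted down in knockout. Of 22 genes 13 fell and 2 rose, the same when adjusted over the list alone (cameraPR adjusted p = 4.66e-11). That call was lost in cameraPR with the log2 fold change as statistic (adjusted p = 0.0588) and held in the other settings. P4ha1, a collagen prolyl hydroxylase, fell by 0.39 and Bnip3, a mitophagy receptor, fell by 0.75 on the log2 scale in the authors' deposited table. The fall of Eno1 (-0.49) is uncertain, since its copy Eno1b rose from 12279 to 22894 in the authors' deposited table. Of the annotation terms, tested after the data were seen, response to hypoxia was enriched among genes that rose (19 of 150, Fisher's exact test adjusted p = 0.00311) and cellular response to hypoxia among genes that fell (13 of 88, Fisher's exact test adjusted p = 0.0433). Both terms were set against all annotated genes whatever their expression. Cholesterol synthesis genes had 4 falls and no rise among 21, and 5 falls when adjusted over the list alone (cameraPR adjusted p = 0.0241). Cyp51 (-0.57) and Nsdhl (-0.57), enzymes of the pathway, were among them in the authors' deposited table. The cholesterol call held by the rank-based test (adjusted p = 0.0411) and in cameraPR without copy pairs (0.0197). In cameraPR it was lost at a correlation of 0.05 (0.113) and with the log2 fold change as statistic (0.355). It was also lost among genes at or above the median value (0.143) and with 10% and 20% added spread (0.101 and 0.201). Of 16 genes of the unfolded protein and amino acid stress response 5 fell and 1 rose, with 6 and 1 when adjusted over the list alone (cameraPR adjusted p = 0.0433). Among the alternative settings this call held only without copy pairs (cameraPR adjusted p = 0.0366). It was lost in all others, from the rank-based test (adjusted p = 0.141) to cameraPR with the log2 fold change as statistic (adjusted p = 0.485). The chaperone genes Hspa5 (-0.19) and Hsp90b1 (-0.17) fell only slightly in the authors' deposited table. Among 12 adipocyte markers 2 fell, the same when adjusted over the list alone (cameraPR adjusted p = 0.00272), namely Lpl (-1.47) and Pparg (-0.84), the lipoprotein lipase and the adipogenic nuclear receptor genes, in the authors' deposited table. By the rank-based test the adipocyte call was lost (adjusted p = 0.122), and it held in the other settings in which it was tested.

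Developmental regulators changed in both directions, and falls outnumbered rises. Of 80 developmental transcription factors 22 fell and 8 rose, with 27 and 14 when adjusted over the list alone (cameraPR adjusted p = 0.0120). In cameraPR that call was lost at a correlation of 0.05 (adjusted p = 0.179) and among genes at or above the median value (28 members, adjusted p = 0.462). It held in the other settings. Shox2, a homeobox gene of the proximal limb, went from 1166 to 398 and Zic1 from 621 to 1391 in the authors' deposited table. Of 38 Hox genes, which set position along the body axis, 4 rose and 4 fell, and 5 rose and 6 fell when adjusted over the list alone (cameraPR adjusted p = 0.431). Hoxa5 (0.66), Hoxb7 (0.53), Hoxb8 (0.67) and Hoxb9 (0.72) rose, while Hoxa10 (-0.51), Hoxa11 (-0.78), Hoxc10 (-0.22) and Hoxd10 (-0.63) fell in the authors' deposited table. Imprinted genes had 6 rises and 2 falls among 28, the same when adjusted over the list alone (cameraPR adjusted p = 0.0282), with Igf2 (0.90), Dlk1 (0.73) and Plagl1 (0.86) rising in the authors' deposited table. Their median log2 fold change was only 0.027. The imprinted call was lost by the rank-based test (adjusted p = 0.343). In cameraPR it was lost at a correlation of 0.05 (0.157), with the log2 fold change as statistic (0.825) and with 10% and 20% added spread (0.164 and 0.395). It held among genes at or above the median value (0.0143) and without copy pairs (0.0235).

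The list of targets of the tumour suppressor p53 was shifted up, and those of DNA replication, mitosis, and cohesin and condensin down, with most members of each not past the threshold. Of 32 p53 targets 9 rose and none fell, and 13 rose when adjusted over the list alone (cameraPR adjusted p = 2.58e-05). That call was lost in cameraPR with the log2 fold change as statistic (adjusted p = 0.102) and held in the other settings. Perp, a membrane protein of the p53 response, had a log2 fold change of 1.25, Trp53inp1 of 0.43 and Phlda3 of 0.26 in the authors' deposited table. Perp is also a member of the epithelial marker list below, where it counts among the rises. Among 11 cell cycle inhibitors 2 rose, and 3 when adjusted over the list alone (cameraPR adjusted p = 0.1002). Cdkn2a, which encodes p16 and p19Arf, went from 573 to 905, and Cdkn1a, which encodes p21, from 10019 to 11034 in the authors' deposited table. Of 53 DNA replication genes 6 fell, and 8 when adjusted over the list alone (cameraPR adjusted p = 5.06e-04). Of 38 mitosis genes 5 fell, and 6 when adjusted over the list alone (cameraPR adjusted p = 2.44e-04). The replication call was lost in cameraPR at a correlation of 0.05 (adjusted p = 0.0525). The mitosis call was lost in cameraPR with the log2 fold change as statistic (adjusted p = 0.0588). Each held in its other settings. Mcm6, a subunit of the replicative helicase, had a log2 fold change of -0.46, Rrm2 of -0.29, Mki67 of -0.28 and the securin gene Pttg1 of -0.82 in the authors' deposited table. Of 24 cohesin and condensin genes 2 fell, Smc2 (-0.25) and Smc4 (-0.22), and 6 when adjusted over the list alone (cameraPR adjusted p = 0.00709), per the authors' deposited table. In cameraPR that call was lost at a correlation of 0.05 (adjusted p = 0.0737) and with the log2 fold change as statistic (0.141). It was also lost among genes at or above the median value (0.108) and with 20% added spread (0.0600), and held in the other settings. Immediate early genes had 4 rises and 1 fall among 16, and 6 and 1 when adjusted over the list alone (cameraPR adjusted p = 0.0241). Their call held by the rank-based test (adjusted p = 0.00294) and in cameraPR without copy pairs (0.0197). In cameraPR it was lost at a correlation of 0.05 (0.104) and with the log2 fold change as statistic (0.355). It was also lost among genes at or above the median value (0.108) and with 10% and 20% added spread (0.0826 and 0.155). Senescence secretory factors went both ways, with 8 rises and 13 falls among 47, and 10 and 15 when adjusted over the list alone (cameraPR adjusted p = 0.667). Igfbp4 rose (log2 fold change 1.27) and Igfbp5 fell (-1.28) in the authors' deposited table.

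**Figure D2:**
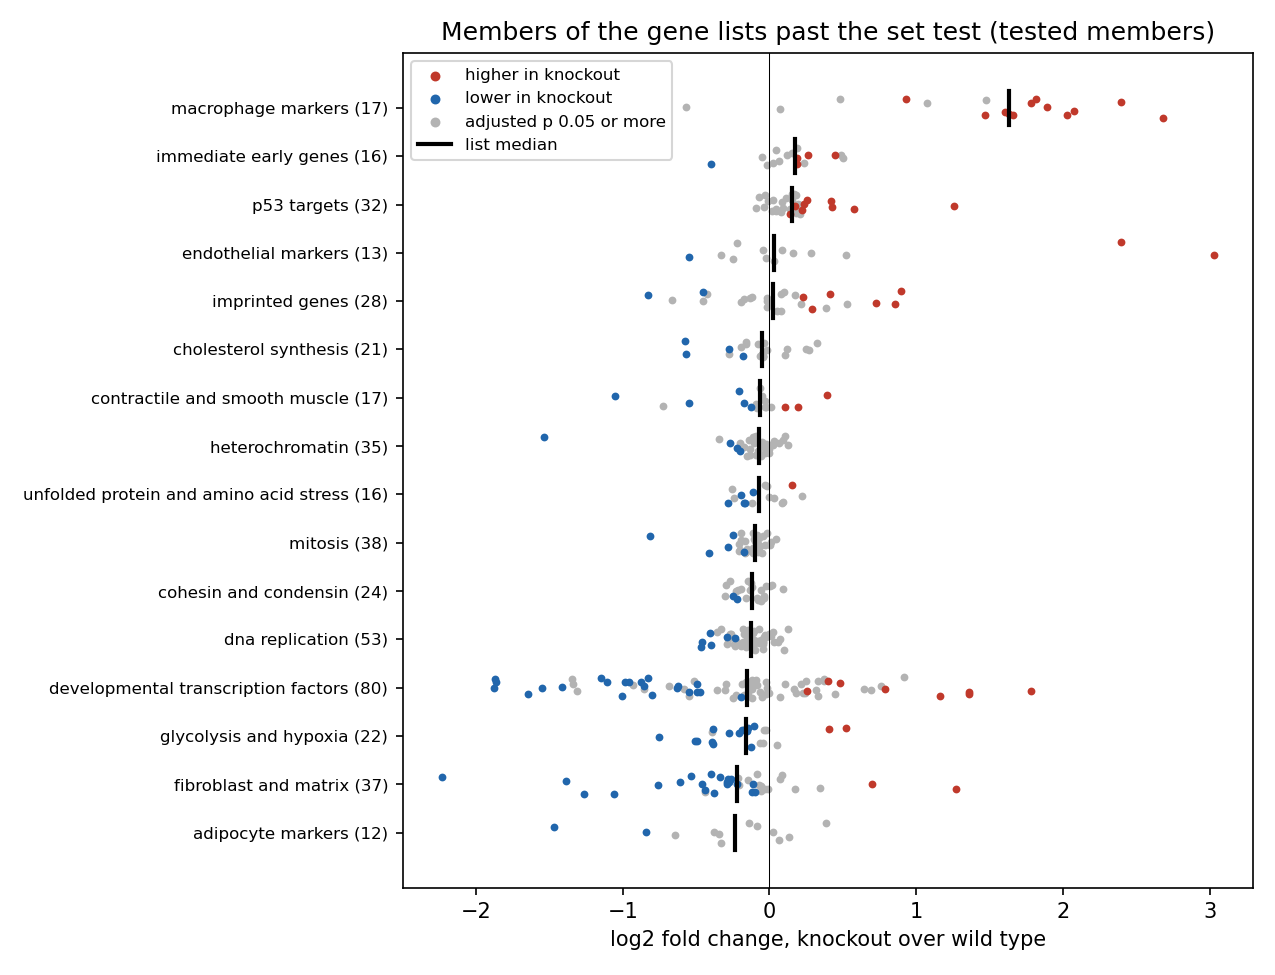
Log2 fold change of each member (horizontal axis) of the 16 gene lists past the set test (vertical axis, tested members in brackets), with red points higher, blue points lower and grey points not past an adjusted p of 0.05, and a black bar at each list's median. The fibroblast and matrix list has 21 blue and 2 red points, and the macrophage list 12 red points.

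Lists on topics that the series description names, which are therefore not independent of the study, had between 0 and 4 members past the threshold. Of 45 genes of homologous recombination and damage signalling 1 fell, also 1 when adjusted over the list alone (cameraPR adjusted p = 0.117), namely Topbp1 (-0.21) in the authors' deposited table. That list passed by the rank-based test (adjusted p = 0.00249) and, shifted down, in cameraPR with 10% added spread (adjusted p = 0.0477). Of 53 genes of end joining and excision repair 1 rose, also 1 when adjusted over the list alone (cameraPR adjusted p = 0.456), and this was Tdg, whose copy Gm9855 went from 729 to 5.96 in the authors' deposited table. Of 35 heterochromatin genes 4 fell, also 4 when adjusted over the list alone (cameraPR adjusted p = 2.44e-04). Without genes of copy pairs, a setting chosen after the data were seen, the cameraPR adjusted p of the heterochromatin list was 0.0796. With the log2 fold change as statistic the cameraPR adjusted p of that list was 0.102. Basal transcription factors (40 genes), folate metabolism (27) and genes associated with amyotrophic lateral sclerosis (29) had no member past the threshold over all genes or adjusted over the list alone (cameraPR adjusted p = 0.503, 0.792 and 0.422), against 1, 2 and 4 at an unadjusted DESeq2 p under 0.05.

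Markers of macrophages were higher in knockout. Of 17 such genes 12 rose and none fell, and 13 rose when adjusted over the list alone (cameraPR adjusted p = 1.53e-15). The lysosomal protease gene Ctss went from 15.7 to 82.4 and Cd68 from 68.7 to 190 in the authors' deposited table, beside Lyz2 above, and the recovered reads of Ctss were 12 and 12 in wild type and 87 and 90 in knockout. Of 13 endothelial markers 2 rose and 1 fell, also when adjusted over the list alone (cameraPR adjusted p = 0.0246). Those were Esam and Cdh5, and Flt1 (-0.55), while Pecam1, chosen after its values were seen, had 2 and 2 recovered reads in wild type and 1 and 3 in knockout. The endothelial list had a median log2 fold change of only 0.033. Its call was lost by the rank-based test (adjusted p = 0.706) and in cameraPR at a correlation of 0.05 (adjusted p = 0.104), and held in the other settings in which it was tested. Epithelial markers had 3 rises and 2 falls among 19, also when adjusted over the list alone (cameraPR adjusted p = 0.912), with the keratin genes Krt8 (-3.71) and Krt18 (-1.78) falling in the authors' deposited table. Other lists did not pass limma cameraPR. They were skeletal muscle (23 genes, 0 up and 1 down, adjusted p = 0.115), cartilage and bone (22, 2 and 3, 0.513), neural and glial (17, 1 and 1, 0.191) and interferon response (34, 1 and 0, 0.639), each with the same counts when adjusted over the list alone. The neural and glial list was shifted up by the rank-based test (adjusted p = 0.0293), and in cameraPR with the log2 fold change as statistic (adjusted p = 0.00222) and with 10% and 20% added spread (adjusted p = 0.0463 and 0.00958). Gonad and sex determination genes (12) had 0 rises and 2 falls, and 3 falls when adjusted over the list alone (cameraPR adjusted p = 0.351), and erythroid markers (7) had no member past the threshold by either adjustment or at an unadjusted DESeq2 p under 0.05, with 0 such genes (cameraPR adjusted p = 0.792). Wnt targets (18) had 1 rise and 2 falls, and 2 and 4 when adjusted over the list alone (cameraPR adjusted p = 0.422). Telomere maintenance genes (24) had 2 rises, and 2 rises and 1 fall when adjusted over the list alone (cameraPR adjusted p = 0.607). Replication-dependent histones (63) had 1 fall and cytosolic ribosomal proteins (103, with some kinases and pseudogenes of similar name) 2 falls, the same when adjusted over the list alone (cameraPR adjusted p = 0.434 and 0.422). The histone list was shifted up by the rank-based test (adjusted p = 0.0318) and in cameraPR with the log2 fold change as statistic (adjusted p = 0.0358). Of 45 centromere and kinetochore genes none passed over all genes or adjusted over the list alone, against 4 at an unadjusted DESeq2 p under 0.05 (cameraPR adjusted p = 0.187), and the list was shifted down by the rank-based test (adjusted p = 0.00482).

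**Figure D3:**
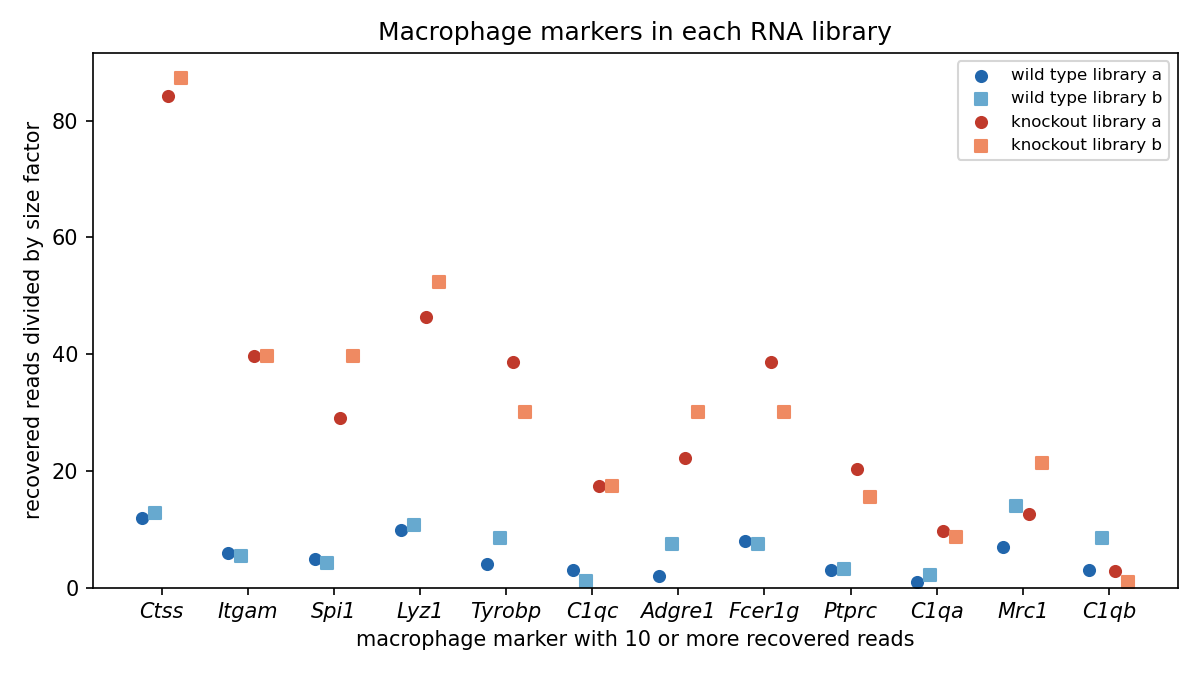
Reads recovered from the deposited values, divided by each library's size factor (vertical axis), for macrophage markers with recoverable reads (horizontal axis), 1 point per library. Blue points are wild-type and red points knockout libraries, whose order within a genotype is not known, and 10 of the 12 markers with 10 or more reads were higher in both knockout than in both wild-type libraries.

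Sex-linked genes were close between the genotypes. Xist, the transcript of the inactive X chromosome, had 2 and 3 recovered reads in wild type and 3 and 0 in knockout, and the Y-linked Ddx3y was at 1331 and 1336 in the authors' deposited table. None of 6 Y-linked genes passed over all genes, 1 rose when adjusted over the list alone and 1 had an unadjusted DESeq2 p under 0.05 (cameraPR adjusted p = 0.667).

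These p-values measure only the spread between these samples, which may be technical, because nothing states that the libraries of a genotype came from separate embryos. With a spread of 10% between cultures added, a setting chosen after the data were seen, 235 genes were higher and 190 lower, and of the 16 list calls that of fibroblast and matrix genes held in all 7 alternative settings, that of macrophage markers held in the 6 in which it was tested, and each of the others was lost in at least 1.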

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

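The settings with added spread, those on recovered reads and those without some genes were chosen only after the result was seen, and the others were listed before the data were examined. Counts of higher and lower genes stayed within 1.5 times of 607 and 750 with a stricter filter (457 and 696), an adjusted p of 0.01 (438 and 533), recomputed adjustment, recentred fold changes, and without macrophage lists and copy pairs (574 and 742). Recomputed adjustment and recentred fold changes left the counts at 607 and 750 and are no test of stability. The recomputed values nearly equal those deposited, and the median removed by recentring was -0.0107 on the log2 scale. The counts moved further with an absolute log2 fold change of 1 or more, which is also the deposited call (175 and 119), with Bonferroni adjustment (249 and 299), and with added spread of 10% (235 and 190) or 20% (68 and 57) between cultures. Fewer genes pass by the construction of these settings. The 38 lists gave 16 calls. They gave 7 at a correlation of 0.05, 8 with the log2 fold change as statistic, 7 of 30 among genes at or above the median value, where the macrophage list had too few members to be tested, 16 by rank (12 of the 16 kept), 14 and 11 with added spread of 10% and 20%, and 15 without copy pairs. The cause was not tested where fewer lists passed with the log2 fold change as statistic. Cbx2 stayed lower in all settings, with a log2 fold change of -3.54 with a pseudocount of 1. Of 89 named genes past the threshold besides Cbx2, 40 lost the call with 10% added spread and 59 with 20%. Added spread leaves the sign of each fold change as deposited, so direction is not tested by it. Among 3290 genes with 10 or more recovered reads, limma called 200 higher and 86 lower, including all 101 called by the authors' DESeq2 with the same direction. With 1 library left out these counts ranged from 0 to 64 higher and from 0 to 57 lower, 0 and 0 without either wild-type library, where the lone sample is assumed to vary like the other group. Of 4407 genes with a mean up to 10, 9 were called, and the deposited fold changes are pulled toward 0 there. No paired analysis was possible because the table holds no values per library for all genes and the order of recovered libraries is unknown. For the same reason another count test, other size factors, the test per library on log2 values with pseudocounts of 0.1 and 10, an estimated correlation and leaving out libraries over the whole table were not run.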

Other observations

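The term enrichment and the tests of every explanation below except that of a larger share of macrophages were chosen only after the result was seen. Among genes that rose, 7 annotation terms were enriched by Fisher's exact test, with positive regulation of angiogenesis (15 of 84 genes, adjusted p = 0.00120), angiogenesis (22 of 189, adjusted p = 0.00311), response to hypoxia (19 of 150, adjusted p = 0.00311) and cell adhesion (24 of 276, adjusted p = 0.0468) among them. Among genes that fell, 24 terms were enriched, with cell adhesion (38 of 276, adjusted p = 2.56e-05), collagen fibril organization (11 of 37, adjusted p = 5.71e-04), embryonic limb morphogenesis (9 of 36, adjusted p = 0.0111) and glycolytic process (8 of 33, adjusted p = 0.0276) by the same exact test. Angiogenesis (22 of 189, adjusted p = 0.0295) and cellular response to hypoxia (13 of 88, adjusted p = 0.0433) were enriched among genes that fell as well, so that vessel, hypoxia and adhesion terms were found in both directions by the exact test. The background was every annotated gene whatever its expression. Calls were far more frequent among high genes (84 of 255 above a mean of 10000, 9 of 4407 up to 10). Terms of genes expressed in these cells could pass in both directions for that reason alone. The limb term held Tbx4, Tbx5, Shox2, Hoxa10 and Hoxa11, and Tbx4 went from 157 to 80.9 and Tbx5 from 45.2 to 17.0 in the authors' deposited table. The class I histocompatibility gene H2-D1 went from 2052 to 857 and the granzyme gene Gzmd from 126 to 401 in the authors' deposited table, both chosen after their values were seen and both members of families of similar genes. Within 5 Mb of Cbx2, 16 of 185 genes passed the threshold (8.65%, against 7.77% elsewhere, Fisher's exact test p = 0.678).

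Macrophage markers rose in knockout. A larger share of macrophages in the knockout cultures is a candidate explanation. In a second list of 73 macrophage genes, written after the first result but before its own values were seen, the median log2 fold change was 0.69, and 43 of 50 members with 10 or more recovered reads were higher in both knockout than in both wild-type libraries, against 31.7% of all 3290 such genes. Not every marker rose. Csf1r was at 245 and 257 in the authors' deposited table, and 2 of the 73 genes were called lower, beside 15 called higher. In wild type Csf1r was above Lyz2 (148) and far above Itgam (8.71) and Adgre1 (7.54) in the authors' deposited table. Its signal may not come from macrophages alone, which could hide a rise, so Csf1r cannot decide on this explanation. In addition, 2 markers with few recovered reads were not higher, C1qb with 3 and 8 in wild type and 3 and 1 in knockout, and Aif1 with 3 and 3 against 0 and 2. Lymphocyte, mast cell and erythroid markers had a median of 0.098 (22 genes). Only 4 lymphocyte, 4 mast cell and 0 erythroid members had 10 or more recovered reads, so more blood cells of every kind stay open too. Whether Cbx2 loss or the preparation of the cultures set the share of macrophages was not tested.

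Some genes fell while a near-identical copy rose, as for Rpl26 with Gm15772 and Eno1 with Eno1b, and reads shared between copies could give such pairs. This was tested in 2 versions. The first took 18 pairs by a broad name rule, which also joined separate members of a gene family, such as Ldha with Ldhb and Slc20a2 with Slc20a1. It therefore could not decide on near-identical copies alone. In this version the sums of the pairs changed by a median of 0.15 on the log2 scale against 0.14 in random pairs (one-sided permutation p = 0.667). After that result the rule was narrowed to 6 pairs and the statistic changed to the log2 of gain over loss, with a median of 0.46 against 1.00 (one-sided permutation p = 0.0587). The narrow rule left out Eif3j2 with Eif3j1 (gain over loss 0.997) and Aph1c with Aph1b (2.71). Neither version passed 0.05, the narrowing was made knowing the first result, and shared reads and true changes of these genes cannot be told apart with so few pairs.

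Hox genes and developmental transcription factors changed in both directions. Of 38 members past the threshold 31.6% were higher (exact 95% interval 17.5% to 48.7%, with genes taken as independent). The 44.7% of rises among all calls lies within that interval. Of 44 members with a mean under 50, 16 had a positive log2 fold change, and 1 was called higher and 4 lower. Rises were not the majority in either group. Genes near silence are seldom called, so this test cannot decide on a general relief of polycomb repression, to which the 12 that rose stay open. Hox genes of groups 10 to 13 had a mean log2 fold change of -0.28 (12 genes, 0 higher and 4 lower) and those of groups 1 to 9 of 0.25 (26 genes, 4 higher and 0 lower), a difference of -0.52, and since the border between groups 9 and 10 was set after the calls were seen, no p is given for it. Single members went the other way without passing the test, Hoxb13 with 10 and 13 recovered reads in wild type and 24 and 33 in knockout, and Hoxd3 with 46 and 44 against 38 and 33. A different mix of body regions in the cultures may give such a shift, and it cannot be told apart from an effect of Cbx2 loss, because the source of the cultures goes with genotype.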
